A study of Mus musculus with 9 samples.

How the data were processed

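Bone marrow HSCs were sorted from mice and libraries were made with SMART-Seq v4 and Nextera XT kits and sequenced on a NextSeq 500, per the labels' protocols. The submitters' processing notes name Trim Galore, STAR 2.5.3a, Partek and the mouse build mm10, with no role or order. The table deposited by the authors holds RPKM values, one per gene and library, although it is named as counts. This was read from the values: they are not whole, each column sums to between 570571 and 604579, and a gene with 1 annotated transcript has values in whole steps that depend on its length. RPKM and FPKM could not be told apart. Each value carries an offset of 0.0001 per transcript, and 58.5% of values stood at the offset. The second sheet of the deposited workbook lists gene symbols under headings such as HSC related; its 18 unnamed columns of values were not used. The groups were taken from the sample titles, since the descriptions end in the same tag, HSC-Y-S, in all groups, those titled old included, so that they do not separate the groups and a wrong title could not be found from them.

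Depth was read from the steps of 7460 genes with 1 transcript of at least 1000 bases. The steps fitted a length reduced by 200 bases, and 83.0% to 86.5% of low values, of up to 10 reads, lay within 0.05 of a whole read. They gave 12.2 to 45.1 (in units of 1000000 reads) per library, a 3.69-fold range. Since only 1 total per library is implied, no read counts were rebuilt and no count test was used. At 1 RPKM a shallow library rests on fewer reads than a deep one, so low genes are less precise there.

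The design fixed before the data were examined was a count test. As the values are RPKM, it was replaced by limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with a mean-variance trend and robust empirical Bayes, 1 model over all 9 libraries with 6 residual degrees of freedom and no covariates. A gene was tested if it reached 1 RPKM in at least 3 libraries, which left 13516 genes. Of the 46628 rows, 2 named no gene and were left out, and 27 carried names turned into dates. Genes of the mitochondrial genome sat at the offset while 4 nuclear-annotated copies of them held 4.1% to 6.64% of the column totals, so the mitochondrial genome list had no tested member. Adjusted p-values are Benjamini-Hochberg over all genes tested, or over lists within a comparison, with a threshold of 0.05.

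Of 33 gene lists fixed before the data were examined, 29 had at least 5 tested members and were tested with camera in limma, with a preset correlation of 0.01 between genes and again with an estimated correlation. The 5 lists in the deposited sheet were adjusted apart. They may have been chosen by the study on these samples and are not taken as independent evidence. Genes were named by a rule fixed in advance. For each comparison it took, among called genes with a mean log2 level of at least 3, complete separation of the groups and no predicted or clone name, the 12 largest rises and 12 largest falls. Where fewer than 3 passed in a direction, the 5 smallest p-values stood in. The level was meant for log2 CPM and was applied to log2(RPKM + 0.5). It added up to 4 called members of each list, up to 4 members with the smallest p of each list that passed, Adrb1, Adrb3, Cdkn1a, Cdkn2a, Slamf1, Kit, Procr, Vwf and Selp. A result for 1 further gene of the rule is not reported here.

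The held-out ageing score used 9 axes, each leaving out 1 saline young and 1 saline old library. The axis weighted each gene by its difference divided by its SD plus the median SD, and the left-out and BRL37344 libraries were placed on it. The covariance of fold changes was set beside 100 simulations by rotation of the residuals, and the overlap of calls beside 20 simulations with no effect. The limma calls, camera and the score with its covariance were tested on simulated data. In simulations of old against young saline over 13516 genes, 43.2% of genes changed 2-fold and 87.0% of those changed 4-fold were found, and 4.5% of calls were false. For BRL37344 old against saline old the shares were 47.4%, 86.4% and 6.7%, and for BRL37344 old against saline young 45.8%, 87.8% and 5.4%. A BRL37344 group simulated at 0.5 of the way scored 0.501 on average over 10 draws. Camera found all 100 shifted lists and called 1 of 100 unshifted ones. The simulated genes varied independently, so this does not show how camera does where the genes of a list vary together. In the data they did, with an estimated correlation of 0.557 in the mitosis list.

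Alternatives were other scalings, filters and pseudocounts, sample quality weights, only the 2 groups compared, the replicate number as a block, and each library left out in turn. A second count test and thinning to equal depth need counts and were not run.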

Results

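RNA was sequenced from haematopoietic stem cells (HSCs), the cells from which all blood lineages arise, sorted from the bone marrow of C57BL/6 mice. The 9 libraries fell into 3 groups of 3: saline young mice of 2 months, saline old mice of 15 to 20 months, and old mice given BRL37344. BRL37344 is an agonist of the β3-adrenergic receptor, one of the receptors for the transmitter of sympathetic nerves, and was given at 2.4 mg per kg per day by osmotic pump for 12 weeks, with the pump changed after 6 weeks. The saline groups too were treated for 12 weeks with the pump changed after 6 weeks. The stated 2 months therefore cannot be the age of the young mice at the end of treatment. The series title concerns the loss of adrenergic nerves in the marrow and the ageing of the stem cell niche. The labels do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. The deposited RPKM values implied depths, in units of 1000000 reads, of 12.2 to 22.5 in saline young, 15.3 to 41.6 in saline old and 16.0 to 45.1 in BRL37344 old, and between 12575 and 12965 genes reached 1 RPKM in a library.

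The first comparison asked how HSCs of old and young saline mice differed. Among the genes that rose most in old HSCs were 2 metallothioneins, a scramblase and the platelet adhesion gene Selp. Plscr2, a phospholipid scramblase, rose from 4.36 ± 0.679 to 135 ± 7.58 RPKM (SD, n = 3; log2 change 4.81 ± 0.23 SE, limma adjusted p = 1.28e-05). Selp, which encodes the platelet and endothelial adhesion protein P-selectin, rose from 8.25 ± 2.16 to 127 ± 16.5 RPKM. The metal-binding proteins Mt2 and Mt1 rose by 5.14 and 3.60 on the log2 scale, Mt1 from 20.8 ± 8.32 to 247 ± 35.4 RPKM. Clu, the secreted chaperone clusterin, rose from 1.64 ± 1.37 to 41.3 ± 22.1 RPKM, and Nupr1, a stress-response transcription regulator, from 11.2 ± 1.42 to 100 ± 5.82 RPKM. Gpr183, an oxysterol receptor, rose from 1.19 ± 0.210 to 22.5 ± 5.36 RPKM. The other largest rises were in Clca3a1, Tm4sf1, Rbm19, the tight junction gene Cldn5 and the glutathione transferase gene Gstm2, with log2 changes of 4.38, 3.79, 3.38, 3.37 and 3.32. Log2 changes are of RPKM plus a pseudocount of 0.5, which understates the change of low genes.

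Cd48, a surface protein that is low on the most primitive HSCs, fell from 19.4 ± 5.73 to 3.76 ± 2.13 RPKM (log2 change -2.29 ± 0.35 SE, limma adjusted p = 0.00957). Plac8 fell from 146 ± 42.2 to 29.8 ± 8.11 RPKM and Ebi3, a subunit of the cytokines IL-27 and IL-35, from 142 ± 15.6 to 31.4 ± 3.50 RPKM. Lst1, a leukocyte transcript, fell from 328 ± 23.0 to 117 ± 4.47 RPKM, and Tnfrsf13c, the receptor for the B cell survival factor BAFF, from 15.6 ± 1.01 to 6.13 ± 0.400 RPKM. Tapt1, Serpina3f, Fscn1, Lgals1, Anxa6, Plxdc2 and Rassf4 also fell, with log2 changes of -1.77, -1.68, -1.62, -1.47, -1.46, -1.42 and -1.28. Of these largest falls, only Plac8, Lst1 and Fscn1 still passed with each library left out in turn. Of the largest rises, all but Rbm19 did, so the falls were the less stable calls. In the list of niche adhesion and homing receptors, which did not move as a set (camera adjusted p = 0.925), 2 of 26 members rose and 1 fell, or 3 and 2 adjusted over the list alone. Those past the test over all genes were Selp, Ackr1, an atypical chemokine receptor, which rose from 0.570 ± 0.438 to 12.6 ± 2.06 RPKM, and Cd47, the surface signal that protects cells from macrophages, which fell from 434 ± 22.6 to 292 ± 22.8 RPKM. Selp and Ackr1 still passed with each library left out in turn, and Cd47 did not.

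Of the gene lists fixed before the data were examined, the aged HSC signature moved most. Of its 38 tested members, 26 rose and none fell, 32 rose adjusted over the list alone, and the median log2 change was 1.83. Its camera adjusted p was 1.78e-41, and the adjusted p was 0.0197 with an estimated correlation between genes; it was the only list of those fixed whose call held that way. In the megakaryocyte and platelet list, 6 of 26 members rose and none fell, or 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 8.34e-05, and adjusted p = 0.163 with an estimated correlation). Its members included Selp, Clu, Itgb3, a platelet integrin, which rose from 12.0 ± 2.65 to 47.3 ± 5.91 RPKM, and Vwf, von Willebrand factor, which rose from 36.9 ± 14.4 to 136 ± 15.7 RPKM. Selp, Clu and Itgb3 still passed with each library left out in turn, and Vwf did not. All 4 genes also belong to the aged HSC signature, so the platelet list is not separate evidence in any comparison. The lymphoid priming list was lower as a set (camera adjusted p = 0.00395, and adjusted p = 0.5 with an estimated correlation), with 14 of 16 members negative; no member passed over all genes, and 4 fell adjusted over the list alone. Its members with the smallest p included Ly86, at 5.71 ± 2.87 in young and 1.04 ± 0.28 RPKM in old, and the transcription factor Sox4, at 20.4 ± 3.85 and 9.53 ± 6.38 RPKM. The B cell markers had a median log2 change of -0.45, with 5 of 8 negative, and did not pass (camera adjusted p = 0.768).

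The HSC identity list did not move as a set (camera adjusted p = 0.953, with a median log2 change of -0.11 and a mean of 0.01): Kit, the stem cell factor receptor, stood at 227 ± 72.2 in young and 198 ± 24.8 RPKM in old, and Procr, the endothelial protein C receptor, at 35.4 ± 0.785 and 40.2 ± 4.99 RPKM. Of its 27 members, 1 rose over all genes, Gprc5c, with a log2 change of 2.22; adjusted over the list alone, 1 rose and 1 fell. Slamf1, which encodes the stem cell marker CD150, stood at 19.5 ± 4.95 and 36.5 ± 6.35 RPKM and did not pass (limma adjusted p = 0.173). The mitosis and DNA replication lists did not pass (camera adjusted p = 0.505 and 0.925). Adrb3, the target of BRL37344, was listed at the offset of the table, which stands for no reads assigned to the gene, in all 9 libraries, and Adrb1 did not exceed 0.039 RPKM. The cell cycle inhibitor and senescence gene Cdkn2a was at the offset in all 9 libraries, and Cdkn1a stood at 2.24 ± 0.794 and 2.86 ± 0.514 RPKM (limma adjusted p = 0.714). Genes of the mitochondrial genome were at the offset too, while nuclear-annotated copies of them held values. The offset alone therefore does not show that a gene was not expressed. Whether reads of Adrb3 or Cdkn2a were assigned to similar copies was not tested.

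**Figure D1:**
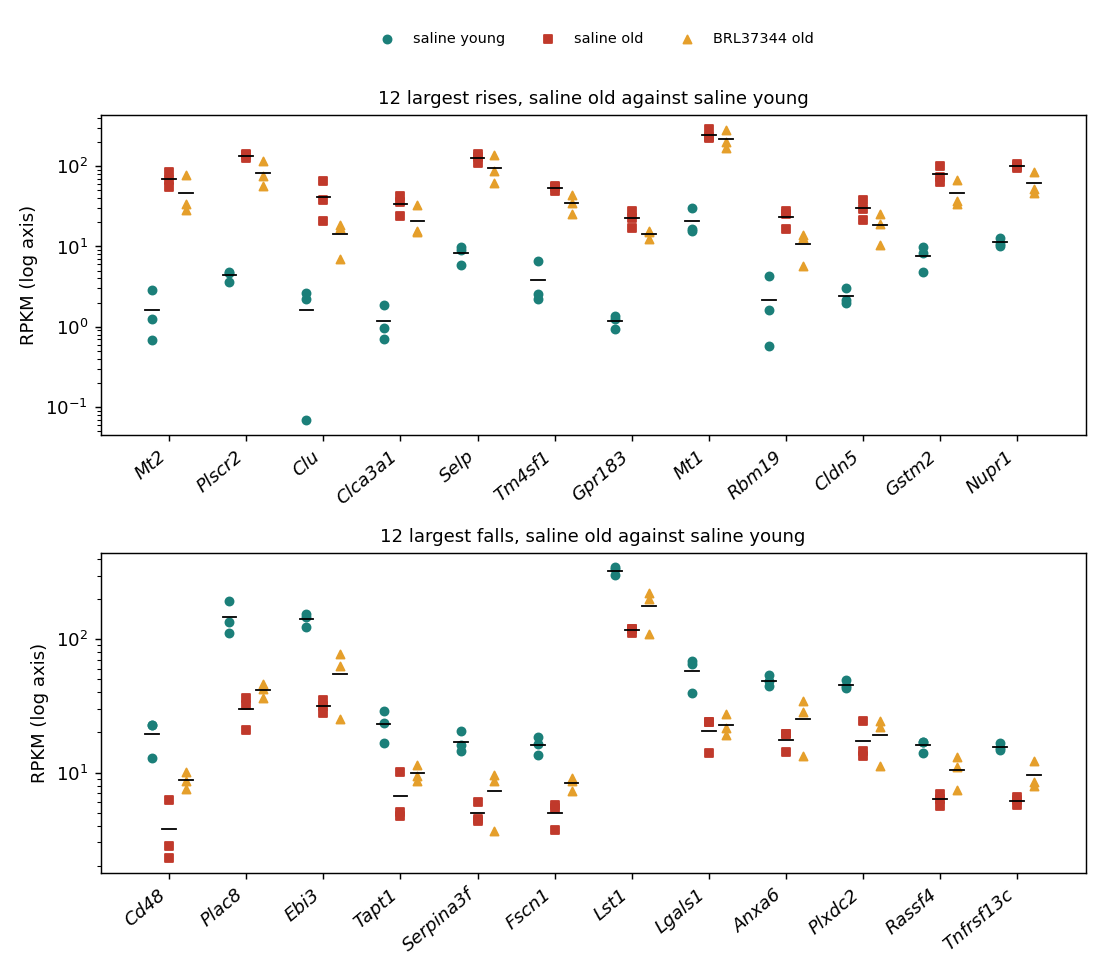
RPKM on a log axis of the 12 genes with the largest rises (top) and the 12 with the largest falls (bottom) between saline young and saline old, with 1 symbol per library, 3 libraries per group, and black bars for group means. Plscr2 stood at 4.36 ± 0.679 RPKM in saline young, 135 ± 7.58 in saline old and 81.8 ± 29.6 in BRL37344 old.

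Granulocyte genes varied strongly among the young libraries and were lower as a set in old HSCs (camera adjusted p = 0.00176, and adjusted p = 0.838 with an estimated correlation). No member of that list passed over all genes or adjusted over the list alone. Mpo, the myeloperoxidase of granulocyte precursors, was at 25, 77.4 and 405 RPKM in saline young and between 1.35 and 1.89 RPKM in saline old. Markers of mature neutrophils, cells that the sort was meant to leave out, followed the same libraries. S100a8 was at 498, 714 and 8654 RPKM in young libraries 1, 2 and 3 and between 337 and 476 RPKM in old ones. The neutrophil list had a camera adjusted p of 0.0160 and an adjusted p of 0.894 with an estimated correlation, and the macrophage list 0.0231 and an adjusted p of 0.894 with an estimated correlation. Neither had a member that passed.

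Over all 13516 genes tested, 159 rose and 54 fell in old HSCs (limma, Benjamini-Hochberg adjusted p of 0.05), and 2032 genes had an unadjusted p under 0.05 where 676 were expected by chance. Every one of the 213 kept the 3 libraries of one group above the 3 of the other. They were chosen by a test of these same libraries, so this is not further evidence for them. Over all genes tested, 20.3% had that property, where chance gives 10%. The count was 586 (170 higher, 416 lower) without saline old replicate 1, 96 without saline young replicate 2 or saline old replicate 2, 116 without saline young replicate 3, 129 without saline old replicate 3, and 1284 (516 higher, 768 lower) with sample quality weights. It was 82, of which 72 were higher, without the 2 libraries highest in neutrophil markers, an alternative chosen after seeing the data.

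The second comparison asked whether a β3 agonist changed the HSCs of old mice. No single gene passed (limma, 0 of 13516 genes, with 762 at an unadjusted p under 0.05 where 676 were expected). The groups lay wholly apart for 10.1% of genes, where chance gives 10%. With sample quality weights 3 genes passed, with only these 2 groups in the fit 2 passed, and with the replicate number as a block or without the 2 libraries highest in neutrophil markers 0 passed. The genes of the rule with the smallest p were higher in BRL37344 for Ptpre, a receptor phosphatase, at 18.7 ± 1.64 RPKM in saline old and 30.4 ± 2.74 in BRL37344 old, and for Foxn3, Iqgap2, Nr3c1, the glucocorticoid receptor, and Dhrs7. They were lower for Srsf7, a splicing factor, at 250 ± 25.5 and 165 ± 20.4 RPKM, Cysltr2, a leukotriene receptor, at 32.5 ± 1.90 and 20.8 ± 1.90 RPKM, and Klhl23, Fgfr1op and Arl6. All 10 had an adjusted p of 0.839. Over all genes tested, the smallest limma adjusted p was 0.0774, for a gene that the limits of the rule on level or name left out.

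As sets, 10 of the 29 lists tested passed with the preset correlation, none held with an estimated one, and 5 passed without the 2 libraries highest in neutrophil markers or without BRL37344 old replicate 2. Of the 10 splits of these 6 libraries, 4 gave as many lists, the real one among them, and the highest other gave 12. The mitosis list was lower, with all 29 members negative and a median log2 change of -0.92 (camera adjusted p = 1.34e-15, and adjusted p = 0.337 with an estimated correlation). Of its members with the smallest p, the checkpoint kinase gene Bub1b stood at 19.5 ± 3.09 and 10.2 ± 3.86 RPKM, and Hmmr at 12.4 ± 0.836 and 5.91 ± 5.44 RPKM. The mean log2 level of this list was 2.83 and 2.75 in BRL37344 old replicates 1 and 2 but 4.11 in replicate 3, inside the range of 3.91 to 4.32 in saline old. The 4 nuclear-annotated copies of mitochondrial genes held 6.64% and 5.97% of the column totals in BRL37344 old replicates 1 and 2. They held 5.54% in replicate 3 and 5.25% to 5.58% in saline old. Whether this difference between libraries bears on the lists was not tested. The DNA replication list had 25 of 28 members negative (camera adjusted p = 5.48e-05, and adjusted p = 0.665 with an estimated correlation), and replicate 3 was again inside the saline old range, at 4.94 against 4.45 to 4.98. Leaving out BRL37344 old replicate 3 gave 39 genes (12 higher, 27 lower) for the whole comparison, among them the mitotic genes Plk1, Ccnb2, Cdc20, Tpx2, Ube2c and Hmmr; of these, Plk1, Ccnb2 and Cdc20 were chosen after their values were seen.

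The aged HSC signature was lower in BRL37344 old than in saline old, with 30 of 38 members negative and a median log2 change of -0.36 (camera adjusted p = 2.39e-06, and adjusted p = 0.337 with an estimated correlation). Plscr2 stood at 135 ± 7.58 in saline old and 81.8 ± 29.6 RPKM in BRL37344 old, Nupr1 at 100 ± 5.82 and 61.2 ± 20.7, and Vwf at 136 ± 15.7 and 70.6 ± 29.0 RPKM. The mean log2 level of the signature was 4.46, 4.50 and 4.731 in BRL37344 old replicates 1, 2 and 3, and replicate 3 was at the low end of the saline old range of 4.73 to 5.10 (exact two-sided permutation p = 0.2). The lymphoid priming list was higher, with 15 of 16 members positive and a median of 0.46 (camera adjusted p = 5.56e-06, and adjusted p = 0.337 with an estimated correlation); 1 member rose adjusted over the list alone. The shift was in 2 of 3 libraries, with means of 4.48, 4.43 and 3.83 in replicates 1, 2 and 3 against 3.43 to 3.86 in saline old (exact two-sided permutation p = 0.2). Its members included Wfdc17, at 55.1 ± 18.7 and 134 ± 46.6 RPKM, and Cd52, at 18.7 ± 4.95 and 53.7 ± 25.2 RPKM. The B cell markers had a median of 0.46, with 7 of 8 positive, and did not pass (camera adjusted p = 0.268). The megakaryocyte and platelet list was lower (camera adjusted p = 0.00611), as were the nuclear oxidative phosphorylation list (7.59e-06) and the histones (0.0267); adjusted p was 0.337, 0.665 and 0.665 with an estimated correlation. The platelet list too was lower in 2 of 3 libraries, at 4.33, 4.19 and 4.74 against 4.59 to 4.76 in saline old (exact two-sided permutation p = 0.3). The cAMP response list was higher (camera adjusted p = 0.00305), with 20 of 24 members positive, among them the clock gene Per1 at 8.81 ± 3.45 and 16.4 ± 4.57 RPKM and the kinase gene Sik1 at 1.95 ± 0.841 and 3.93 ± 1.24 RPKM. The NF-kB list (0.00991) and the granulocyte list (0.0131) were higher too; for these 3 lists adjusted p was 0.337, 0.5 and 0.665 with an estimated correlation. Outside lymphoid priming, no member of these 10 lists passed over all genes or adjusted over the list alone. Neutrophil markers had a mean log2 level of 1.02, 6.08 and 4.68 in BRL37344 old replicates 1, 2 and 3, against 3.06 to 3.65 in saline old. The plasma cell transcript Jchain was at 2.09, 263 and 6.16 RPKM in BRL37344 old replicates 1, 2 and 3, and between 0.928 and 16.3 RPKM in saline old.

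**Figure D2:**
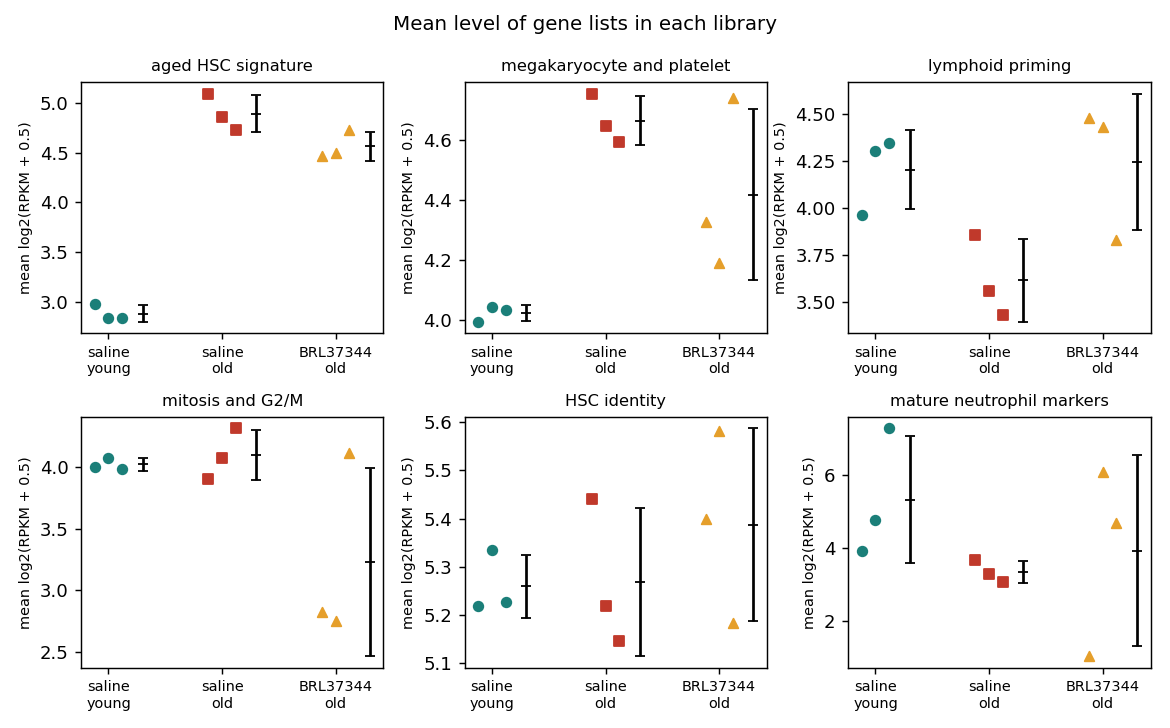
Mean log2(RPKM + 0.5) of 6 gene lists in each library, with 1 symbol per library, 3 per group, and the group mean ± SD beside them. The mitosis list stood at 2.83 and 2.75 in 2 BRL37344 old libraries and at 3.91 or above in the other 7 libraries, and the neutrophil markers ranged from 1.02 to 7.28.

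The third comparison set BRL37344 old against saline young, and so combined age and drug. Here 94 genes rose and 10 fell (limma, adjusted p of 0.05), and 84 of the 94 and 6 of the 10 were among the 159 and 54 called in the same direction in saline old. Independent lists of these sizes would share 1.11 and 0.04 genes, and simulated libraries with no effect against the same young libraries shared 0.05 genes on average and at most 1, but called only 0.35 and 0.2 genes on average, so that they could share few. Part of the excess may come from the shared saline young libraries, which were too few to split into parts of 2. Across genes, which are not independent replicates, the fold changes of both comparisons had r = 0.733 and a covariance of 0.200, and the shared libraries alone gave 0.507 and 0.077.

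Of the 12 largest rises, Plscr2, Mt2, Mt1, Selp, Clca3a1, Gpr183, Tm4sf1, Cldn5 and Gstm2 were also among the 12 largest in saline old. The other 3 were H2-Eb1, an MHC class II gene, from 13.7 ± 4.25 to 121 ± 61.6 RPKM, Fhdc1, from 2.38 ± 1.37 to 17.4 ± 4.28, and Aldh1a1, an aldehyde dehydrogenase, from 34.1 ± 11 to 218 ± 38.9 RPKM. Socs2, an inhibitor of cytokine signalling, fell from 49.3 ± 4.13 to 7.20 ± 4.23 RPKM, with 14.3 ± 8.83 RPKM in saline old. Plac8, Hmga1, Epb41l4b, Mc5r, Serpina3g and Wasf2 fell too, with log2 changes of -1.77, -1.23, -1.06, -1.06, -1.01 and -0.99. Of these falls, that of Socs2 included, only Plac8 and Serpina3g still passed with each library left out in turn. All of the 12 largest rises did. In the aged HSC signature, 20 of 38 members rose, or 29 adjusted over the list alone (camera adjusted p = 1.47e-46, and adjusted p = 0.0144 with an estimated correlation). The megakaryocyte and platelet list had 3 of 26 risen, Selp, Itgb3 and Plek, or 5 adjusted over the list alone (camera adjusted p = 0.00635, and adjusted p = 0.413 with an estimated correlation). The interferon response list was lower, with 25 of 32 members negative and 4 fallen adjusted over the list alone (camera adjusted p = 8.32e-05, and adjusted p = 0.516 with an estimated correlation); Ifit1 stood at 12.9 ± 0.473 in young and 6.84 ± 1.03 RPKM. The total of 104 genes was 57 without saline young replicate 2, 62 without saline young replicate 3, 64 without BRL37344 old replicate 2, 163 (104 higher, 59 lower) without BRL37344 old replicate 3, 169 with sample quality weights, and 42 without the 2 libraries highest in neutrophil markers.

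Whether BRL37344 moved old HSCs toward young ones was measured for the ageing genes. Of the 159 genes higher in saline old, 136 (85.5%) lay lower in BRL37344 old than in saline old, with a median log2 change of -0.34 against an ageing change of 1.81. Of the 54 lower genes, 51 (94.4%) lay higher, with a median of 0.52 against -1.44. Both sets were chosen with the same saline old libraries, which by itself moves them toward young. With 1 saline old library left out of the choice and used alone for the second difference, the share toward young was 39.4%, 79.2% and 65.9% for saline old libraries 1, 2 and 3. For the genes higher in old it was 77.6%, 78.2% and 61.8%, and for the lower ones 23.8%, 83.3% and 81.5%; without library 1, 416 of the 586 genes were lower ones.

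A score free of that overlap, from libraries held out of the ageing axis, was 0 ± 0.138 in saline young and 1 ± 0.226 in saline old by scaling, and 0.755 ± 0.179 in BRL37344 old (SD, n = 3). BRL37344 old differed from saline old by -0.24 (exact two-sided permutation p = 0.3, where the smallest p that 3 against 3 allows is 0.1). The covariance across genes of the ageing and BRL37344 fold changes was -0.115, where shared saline old libraries with no effect gave -0.0746 ± 0.0182 (SD of 100 simulations) and 3 of the 100 were as low. With 1 library left out, the gap was narrowest at -0.129 against a simulated -0.121 without saline old replicate 2, and -0.0919 against -0.0767 without BRL37344 old replicate 2. It was widest at -0.182 against -0.109 without saline old replicate 1, and -0.131 against -0.0733 without BRL37344 old replicate 1. The correlation was -0.528, against -0.494 simulated, and 32 of the 100 were as low.

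**Figure D3:**
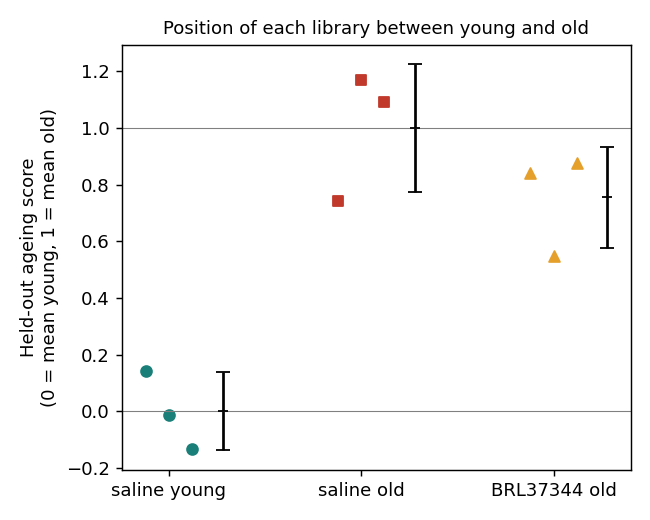
Held-out ageing score of each library, scaled so that the saline young mean is 0 and the saline old mean is 1, with 3 libraries per group and the mean ± SD beside them. The BRL37344 old libraries sat between 0.549 and 0.875, and the saline old ones between 0.743 and 1.17.

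Positions are from the GENCODE vM21 annotation of mouse build GRCm38, the assembly called mm10 in the submitters' processing notes. Plscr2 spans chromosome 9 from 92275602 to 92297752, Selp chromosome 1 from 164115264 to 164150026, and Mt2 and Mt1 chromosome 8 from 94172664 to 94173568 and from 94179082 to 94180327. Vwf spans chromosome 6 from 125546774 to 125686679, Cd48 chromosome 1 from 171682009 to 171705258, and Plac8 chromosome 5 from 100553725 to 100572245. These genes are annotated as protein-coding genes, and each value covers the whole gene. Mt1 and Mt2, Clca3a1, Gstm2, Serpina3f and Serpina3g, the MHC class II genes and the histones belong to families with similar copies, among which reads may have been split, so their values are less certain.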

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

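The pseudocounts of 0.1 and 1, the fit without robust empirical Bayes and the fit without the 2 libraries highest in neutrophil markers (saline young replicate 3 and BRL37344 old replicate 2) were chosen after seeing the data; the other alternatives were planned. Between saline old and saline young, 213 genes passed, and 140 without a filter on low values (genes above 0.01 RPKM in any library), where more genes share the adjustment, 1284 with sample quality weights, 82 without the 2 neutrophil-high libraries, and 96 to 586 with 1 library left out. Between BRL37344 old and saline old, 0 passed, and 3 with sample quality weights (Gm24161, Gm24786 and Sephs1), 2 with only the 2 groups compared (Gm24991 and Gm25328), 1 with a pseudocount of 0.1 (Gm24786), and 0 to 39 with 1 library left out; these genes were named after their values were seen. Between BRL37344 old and saline young, 104 passed, and 169 with sample quality weights, 42 without the 2 neutrophil-high libraries, and 57 to 163 with 1 library left out. Gene lists past the threshold numbered 13, 10 and 11 in these comparisons, 1, 0 and 1 with an estimated correlation, and 3, 0 and 1 with fry, which tests each list by itself and not against other genes. With 1 library left out they ranged from 5 (without saline old replicate 3) to 13, from 5 (without BRL37344 old replicate 2) to 16 (without BRL37344 old replicate 1) and from 8 to 12, and without the 2 neutrophil-high libraries the second comparison had 5. The cause of these changes was not tested, except where given.

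The score difference of -0.24 ranged from -0.30 to -0.14 (without BRL37344 old replicate 2) with 1 BRL37344 library left out, with exact two-sided permutation p between 0.3 and 0.4. The covariance of -0.115 was -0.0957 with a filter of 5 RPKM, beside a simulated -0.0555. With 1 library left out it ranged from -0.182 (without saline old replicate 1, beside a simulated -0.109) to -0.0919. Beside its simulated value it was -0.129 and -0.121 without saline old replicate 2, and -0.0919 and -0.0767 without BRL37344 old replicate 2. With 1 library left out in turn, 19 of 37 named called genes between saline old and saline young passed every time. Between BRL37344 old and saline young 18 of 26 did. Of called lists, 4 of 13 between saline old and saline young did (aged HSC, epigenetic, lymphoid priming and platelet). Between BRL37344 old and saline old 5 of 10 did (aged HSC, cAMP, lymphoid priming, mitosis and nuclear oxidative phosphorylation). Between BRL37344 old and saline young 4 of 11 did (aged HSC, ribosomal protein, stroma and mitosis). The other called lists did not pass every time. None of these genes and no called list changed direction. Other scalings moved the median of all genes by less than 0.1.

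The replicate numbers are shared across groups, and most libraries with the same number did not deviate together. For these pairs r ranged from -0.052 to 0.19, 2 of 9 exceeded 0.1, and 4 of 9 libraries were closest to their own number. Replicate 1 was a partial exception. Saline young replicate 1 had r of 0.105 and 0.19 with replicate 1 of saline old and BRL37344 old, which had 0.012 with each other. On the second principal component (15.9% of variance) replicate 1 stood at 27.64, 23.64 and 36.01 in saline young, saline old and BRL37344 old. The other libraries lay between -28.83 and 2.84, and the cause was not tested. With the replicate number as a block, 174, 0 and 92 genes passed, and 13, 11 and 13 lists, while the covariance was -0.115. A second count test and thinning to equal depth were not run because the values are not counts. Depth limits low genes most, since 1 RPKM rests on fewest reads in saline young replicate 1, with an implied depth of 12.2 in units of 1000000 reads.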

Other observations

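Tests here followed predictions written before their results were seen, except the test of dilution by other cells, which was chosen afterwards. The requirement that a bound be passed by more than the spread was also added afterwards, and it left open dilution and, for mitosis genes, dependence on 1 library. The levels by library set beside the neutrophil tests and beside depth were also looked at afterwards. Further gene lists differed with age. The interferon response list was lower in saline old than in saline young, with 28 of 32 members negative and 1 fallen adjusted over the list alone (camera adjusted p = 0.0148, and adjusted p = 0.838 with an estimated correlation); Isg15, a ubiquitin-like interferon product, stood at 27.6 ± 4.24 and 18.6 ± 3.89 RPKM. The epigenetic regulators were lower, with 21 of 25 negative and 1 fallen adjusted over the list alone (0.0152, and adjusted p = 0.183 with an estimated correlation), and the DNA methyltransferase gene Dnmt3a stood at 19.2 ± 2.76 and 9.60 ± 2.21 RPKM. The p53 and DNA damage list was higher (0.0462, and adjusted p = 0.5 with an estimated correlation), with 1 of 23 members risen, Gadd45g, from 3.48 ± 0.337 to 16.2 ± 2.21 RPKM, or 2 risen and 1 fallen adjusted over the list alone. Gadd45g did not pass with every library left out in turn. The apoptosis gene Bbc3 in that list stood at 7.05 ± 2.92 and 2.25 ± 0.0490 RPKM. The unfolded protein, stroma, ribosomal protein and nuclear oxidative phosphorylation lists were higher (camera adjusted p = 0.0281, 0.0405, 0.0149 and 0.00252), with no member past the test over all genes or adjusted over the list alone, and adjusted p was 0.678, 0.705, 0.894 and 0.894 with an estimated correlation.

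In BRL37344 old against saline young, mitosis, DNA replication, macrophage and histone lists were lower (camera adjusted p = 5.7e-09, 0.000233, 0.0246 and 0.048), and ribosomal protein, stroma, quiescence and p53 lists were higher (7.36e-06, 0.000498, 0.0414 and 0.0414). With an estimated correlation adjusted p was 0.516, 0.618, 0.627 and 0.627 for the former and 0.618, 0.413, 0.577 and 0.505 for the latter. The deposited lists may have been chosen by the study on these samples and are not taken as independent evidence. Their platelet list was higher in saline old than in saline young (camera adjusted p = 2.34e-07, and adjusted p = 0.0768 with an estimated correlation), with 3 of 6 members risen, Selp, Sdpr and Fhl1, or 4 adjusted over the list alone, and higher in BRL37344 old than in young (1.75e-07, and adjusted p = 0.0938 with an estimated correlation). Their lymphoid list was lower with age (0.0230, and adjusted p = 0.137 with an estimated correlation) and higher with BRL37344 (0.00483, and adjusted p = 0.157 with an estimated correlation). Their myeloid list was lower with age (0.0107, and adjusted p = 0.0768 with an estimated correlation), with 1 of 11 members fallen, Ms4a6b, or 3 adjusted over the list alone. Ms4a6b did not pass with every library left out in turn. The HSC and erythroid lists of the study did not pass with age (camera adjusted p = 0.560 and 0.278).

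The ageing genes lay closer to young in BRL37344 old. The shared saline old libraries may account for the pattern, since with 1 of them held out the share toward young averaged 61.5% with an SD of 20.3 over the 3 libraries, the lowest resting on the lower genes without library 1. Of the genes lower in old, 94.4% lay higher in BRL37344 old with the mean of 14 neutrophil markers as a covariate (median 0.518 before and 0.502 after). The share was 94.4% without the covariate too. These genes were chosen as low in the same saline old libraries, so the share cannot count against neutrophil transcripts. They stood 0.58, 0.65 and 0.36 above saline old in BRL37344 old replicates 1, 2 and 3, where the markers were at 1.02, 6.08 and 4.68. The HSC identity list had a median change of 0.095, and its members spread with an SD of 0.39. That SD is between genes and does not measure the error of the median. The mean log2 level of the list was 5.39 ± 0.199 in BRL37344 old and 5.27 ± 0.154 in saline old (SD, n = 3). As the libraries overlapped (exact two-sided permutation p = 0.6), RNA of other cells stays open. An effect of the drug stays open as well, and it cannot be told apart from the shared libraries or RNA of other cells.

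Mitosis genes were lower in 2 of 3 BRL37344 libraries; fewer dividing cells after the drug is a hypothesis that was not tested. Deviations within groups of the mitosis level and of log2 depth had r = 0.585 and rho = 0.567 over 9 libraries (exact two-sided permutation p = 0.292 and 0.255 over 216 orders within groups). Lower levels in deeper libraries would need a negative r, and r was 0.491 without the 2 farthest libraries. The permutation did not set r apart from 0, and the mitosis level varied mostly within BRL37344 old (SD 0.768, against 0.0493 in saline young and 0.205 in saline old). The correlation does not decide on sequencing depth, but levels at similar depth argue against depth as the source of the 2 low levels. BRL37344 old replicate 1, at an implied depth of 16.03 (units as above), stood at 2.825. Saline old replicates 1 and 2, at depths of 15.33 and 17.0, stood at 3.907 and 4.079. BRL37344 old replicate 2, at a depth of 33.65, stood at 2.748. Saline old replicate 3, at 41.56, stood at 4.316. With 1 library left out, the median log2 change ranged from -1.37 to -0.615. It was -0.673 and -0.615 without BRL37344 old replicates 1 and 2, so neither of these low libraries alone carried the whole fall. The weakest value passed the bound set for it by less than its spread of 0.076. That spread is over the genes of the list and not between libraries, so the bound does not decide dependence on 1 library. A group difference cannot be told apart from a fall in 2 of 3 libraries. The mean level differed by -0.87 (exact two-sided permutation p = 0.3).

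Neutrophil transcripts, highest in saline young replicate 3, could have lowered genes in saline old by their absence, but the 54 genes called lower kept 101.2% of their median change with the neutrophil markers as a covariate (-1.44 and -1.46, with an SD of 0.724 before and 0.794 after), while the granulocyte list went from -1.79 to -0.665. The called genes stood 1.34, 1.36 and 1.48 above saline old in saline young replicates 1, 2 and 3, where the markers were at 3.92, 4.77 and 7.28. With 1 residual degree of freedom fewer, 22 of the 54 lower genes and 88 of the 159 higher ones still passed. Without the 2 neutrophil-high libraries 10 lower and 72 higher genes were called, while the 54 had a median of -1.33 with fewer libraries. The neutrophil markers still differed by -1.01 there. This covers the called genes only. Calling favours genes with a small spread within groups, so genes that follow the markers could hardly be among the 54. The covariate was therefore likely to change them little, and it cannot decide for other genes. An effect of age stays open and is a hypothesis.

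Each pair of groups allows 10 splits of its 6 libraries, too few for a share under 0.05. Between saline old and young, 1 split, the real one, gave as many as 213 genes, and the highest other gave 1; for lists 1 split gave as many as 13, and the highest other 7. Between BRL37344 old and saline young, 1 split gave as many as 104 genes, with a highest other of 5, and 2 splits gave as many as 11 lists, with a highest other of 12. Between BRL37344 old and saline old, 4 splits gave as many as 10 lists, with a highest other of 12, so that number of lists was not particular to the real grouping. All 10 splits gave as many as 0 genes, which no split could fail to do. The highest other counts of genes there were 119, with saline old replicate 1 grouped with BRL37344 old replicates 2 and 3, and 83, with it grouped with replicates 1 and 2; the cause was not tested.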
